A study of Homo sapiens with 2 samples.

How the data were processed

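JARID2 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MDA-MB-231, a human triple-negative breast cancer line. The labels name 2 libraries, 1 precipitated with a polyclonal antibody against JARID2 and 1 of input DNA that was not precipitated. Per the labels' protocols, chromatin was fixed with formaldehyde and sonicated, and libraries were made with a transposase-based kit and PCR. Files of 1 library, the JARID2 ChIP, were analysed here, and no value of the input library itself was used. How the authors used the input in peak calling is not given in the sources used here. Each group held 1 library, so no value has a replicate check.

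Per the submitters' processing notes, bcl2fastq, Bowtie 0.12.8, MACS, MACS2 and ChIPseeker were used with the hg19 build. Which peak caller version made the list, and the aligner parameters, duplicate filter and calling thresholds, are not given in the sources used here. The columns have the layout of MACS version 1. The deposited tag count is a whole number per peak and is not normalised. The deposited fold enrichment is a linear ratio of ChIP to the caller's background, per the file headers. The deposited false discovery rate (FDR) is a percent, per the file headers, which in MACS version 1 is an empirical rate from exchanging ChIP and control. The header of the remaining deposited score was unreadable. From its place and its smallest value of 30 it was read as −log10 p multiplied by 10. Per the file headers, each peak carries the nearest transcript, its Ensembl gene and an annotation class with promoter bins reaching 3 kb from a transcription start site (TSS).

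The depth of the libraries is unknown, since the list holds only peaks. The peaks held 1000395 tags in all, with a median of 12 per peak, for which the 95% Poisson interval is 6.20 to 20.96. Exact Clopper-Pearson intervals were given for shares of peaks. All such intervals cover counting error only, because PCR copies are not independent molecules. Weak peaks rest on few tags, which makes fold enrichment take repeated values. The value 6.18 alone was given to 7555 peaks (11.3%).

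Symbols in the list were matched to the 20033 protein-coding genes of the RefSeq table of GRCh38.p14 on chromosomes 1 to 22, X and Y, by symbol or by a synonym belonging to 1 gene. The table supplied names and numbers of transcripts but no coordinates. Of 26257 symbols in the list, 11300 matched a protein-coding gene, and 45.2% of the peaks were given to such a gene. A promoter peak was a peak of the promoter class, within 3 kb of a TSS. Each peak was given to 1 nearest transcript, so promoters shared by neighbouring genes count for 1 of them and exon peaks can carry the name of a small RNA inside the host gene.

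24 gene lists, the tests and the rule for the genes named were fixed before the data were examined. The lists were HOX cluster genes, other developmental transcription factors, PRC2 subunits, PRC1 subunits, JmjC demethylases, mesenchymal, epithelial, luminal and basal genes, TGF-beta/BMP, WNT, Notch and Hippo genes, cell cycle genes, tumour suppressors, ribosomal proteins, proteasome subunits, interferon and hypoxia response genes, liver genes, ion channels and receptors, olfactory receptors, keratin-associated proteins and numbered zinc finger genes. Members with a promoter peak were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Each share was also placed among 10000 random lists matched on the number of RefSeq transcripts per gene, since gene lengths of the build were not used here. The highest promoter fold enrichment per gene was compared by a two-sided permutation test of medians with 100000 resamples, for lists with at least 5 such genes. Genes are not replicates, so these p-values describe this peak list only. The strongest 25% of peaks was compared with the rest by Fisher's exact test, two-sided.

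The genes named are every PRC2 subunit measured, in each other list up to 4 members with the largest promoter fold enrichment (for lists past the threshold with fewer genes than expected, the count only), the 10 peaks of largest fold enrichment with 1 per gene, the 10 protein-coding genes with the strongest peak within 1 kb of a TSS, and the 5 genes with most peaks. Some genes that the rule picks are not reported here. Genes named outside this rule are said to be so. The rule's score alternatives asked for −log10 q or p, and p was used because the FDR is an empirical percent. Alternatives were a score threshold, a fold threshold, the top 25%, a promoter reach of 1 kb, other backgrounds, any peak in place of a promoter peak, and merging of neighbouring peaks. FDR limits of 5% and 10% and the removal of 3 loci were added after the data were examined. Base composition and random placement of peaks needed the hg19 sequence and were not run.

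On simulated data over 20033 genes, the list comparison called 94.7% of lists given 3 times the odds and 86.7% of those with the odds divided by 3, against 2.00% of unchanged lists. Over 3000 genes, the fold comparison called 100.0% of 10 lists raised 1.5 times and 6.67% of 30 unchanged lists. All simulated lists held 40 or more genes, so these rates do not cover smaller lists such as the 14 PRC2 subunits. The simulated fold comparison was adjusted over fewer lists than the 23 of the real one, so its rates may be too high for it. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.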

Results

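JARID2, an accessory subunit of the Polycomb repressive complex PRC2, was mapped across the genome of MDA-MB-231 breast cancer cells. The series asks where JARID2 sits on chromatin in these cells. It has 1 JARID2 ChIP library and 1 input library, and the data are the authors' annotated list of 67071 peaks on hg19. With 1 ChIP library there was no replicate, and every fold enrichment, tag count and FDR below is the authors' own value for a peak. The library depth is unknown.

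Most of the listed peaks were weak, and a small set was strong. The median peak was 510 bp wide (interquartile range 443 to 634), held 12 tags (10 to 16) and had a fold enrichment of 5.95 (5.28 to 6.85). Tags per peak ranged from 9 to 1299 and fold enrichment from 2.62 to 158.75. The peaks covered 38.2 Mb. The median FDR was 44.2%, and 47165 peaks (70.3%) had an FDR above 40%. An FDR of at most 5% was reached by 834 peaks (1.24%), of which 253 had an FDR of 0.

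Promoters made up a larger share of the strong peaks than of the weak ones. Over all peaks, 20.5% (95% exact interval 20.2 to 20.8) lay in promoters, 37.2% in introns, 36.6% in distal intergenic sequence and 3.96% in exons or untranslated regions (UTRs). Among the 253 peaks with an FDR of 0, promoters took 81.0% (75.6 to 85.7), introns 4.35% and distal intergenic sequence 5.14%. The promoter share was 66.3% (62.3 to 70.1) for an FDR above 0 and up to 5%, 40.9% (38.7 to 43.1) up to 20%, 22.1% (21.5 to 22.7) up to 40% and 18.2% (17.9 to 18.6) above that. In the top 25% by fold enrichment, 21.8% of 16887 peaks were promoter peaks against 20.1% of the other 50184, an odds ratio of 1.11 (1.07 to 1.16, Fisher's exact test, two-sided, p = 1.19e-06). Ranking by p gave 27.2% against 18.3% and an odds ratio of 1.67 (1.60 to 1.74, Fisher's exact test, two-sided, p = 1.64e-128).

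**Figure D1:**
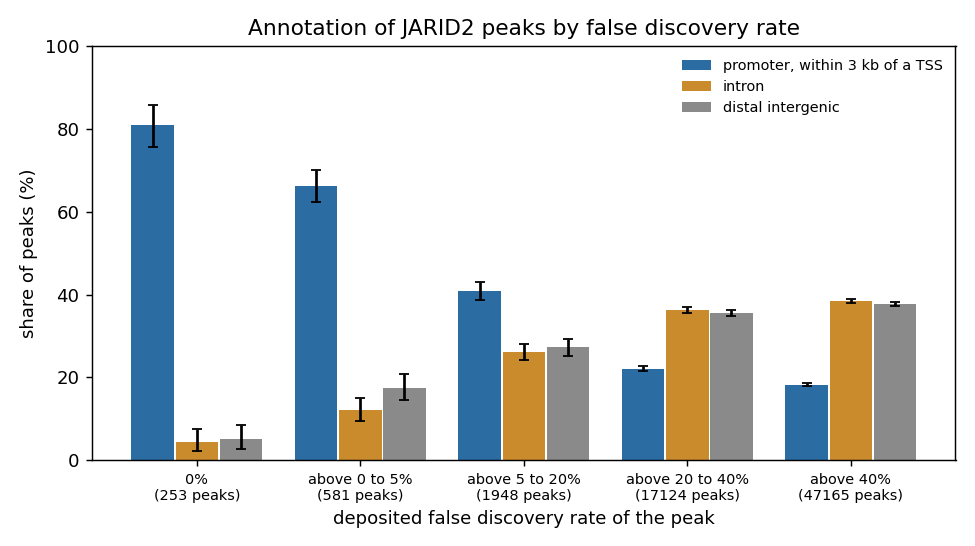
Share of peaks (%, bars, with 95% exact binomial intervals) in promoters within 3 kb of a TSS, in introns and in distal intergenic sequence, for 5 classes of the deposited FDR. The promoter bar falls from 81.0% at an FDR of 0 to 18.2% above an FDR of 40%, while the intron bar rises from 4.35% to 38.4%.

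The strongest peaks lay at GH1, JARID2, EZH2 and KDM1A. The largest fold enrichment, 158.75 with 779 tags, was on chromosome 17 (61993755 to 61994971), 2272 bp from the TSS of the growth hormone gene GH1. A peak at an internal JARID2 start site on chromosome 6 (15500789 to 15501740) reached 137.44 with 583 tags. A peak named for RNU7-20P, a small RNA pseudogene inside the EZH2 gene, reached 113.02 on chromosome 7 (148514765 to 148515497). KDM1A, a histone lysine demethylase gene, had 84.67 on chromosome 1 (23409610 to 23410322). EZH2P1, an EZH2 pseudogene, had 75.19 on chromosome 21 (36971833 to 36972362), and EZH2 itself 64.5 on chromosome 7 (148510789 to 148511833). A peak of 60.85 (chromosome 6, 15519961 to 15520741) was annotated to a 3′ UTR and named for DTNBP1. IKZF3, a lymphoid transcription factor gene, followed with 50.3, then TOPBP1, a DNA damage response gene, with 49.03 on exon 11 (chromosome 3, 133362618 to 133363512), and RNF130 with 44.63. All of these 10 had an FDR of 0. Fold enrichment alone does not show that JARID2 binds chromatin at these sites. The closing section argues against such binding as at other loci for exon and UTR peaks at JARID2 and EZH2. The GH1 peak was not tested.

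Among protein-coding genes with a peak within 1 kb of a TSS, JARID2 (137.44), KDM1A (77.61), IKZF3 (50.3) and RNF130 (44.63) ranked first. GLS2, a glutaminase gene, had 43.27 with 84 tags (chromosome 12, 56881797 to 56883196). CSTF3, which encodes an mRNA cleavage factor subunit, had 36.81, ZNF785 30.02 and the nucleoporin gene SEH1L 29.14. Each of the peaks named here overlapped a TSS and had an FDR of 0.

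Strong peaks in the JARID2, EZH2 and KDM1A loci lay on exons, UTRs and promoter-class sequence. At JARID2, exon 7 of 18 carried 1299 tags, the most of any peak, at 123.69-fold (chromosome 6, 15496274 to 15497479). Exon 14 had 91.83, exon 6 had 74.91, and peaks in the 5′ UTR had 76.4, 58.21, 26.77 and 25.01. Peaks on exons 10 and 17 were weak, at 8.82 (FDR 35.7%) and 8.32 (FDR 43.9%). The 6 intronic JARID2 peaks had a median fold enrichment of 5.58, and 0 of them reached an FDR of 5%. The 1 intronic peak in each of the EZH2 and KDM1A loci did not reach it either, against 5 and 2 exon or UTR peaks that did. The 3 loci held 13 of the 20 peaks of largest fold enrichment, and their 39 peaks held 4509 tags (0.451% of the tags in peaks). The JARID2 span used here ended at 15517799, the end of the peak on exon 17 of 18, so it may stop short of the gene's end. The 3′ UTR peak of 60.85 named for DTNBP1 lies just beyond that peak and is counted outside the 3 loci here. Whether it lies in JARID2 was not checked, so the counts for that locus may be too low.

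**Figure D2:**
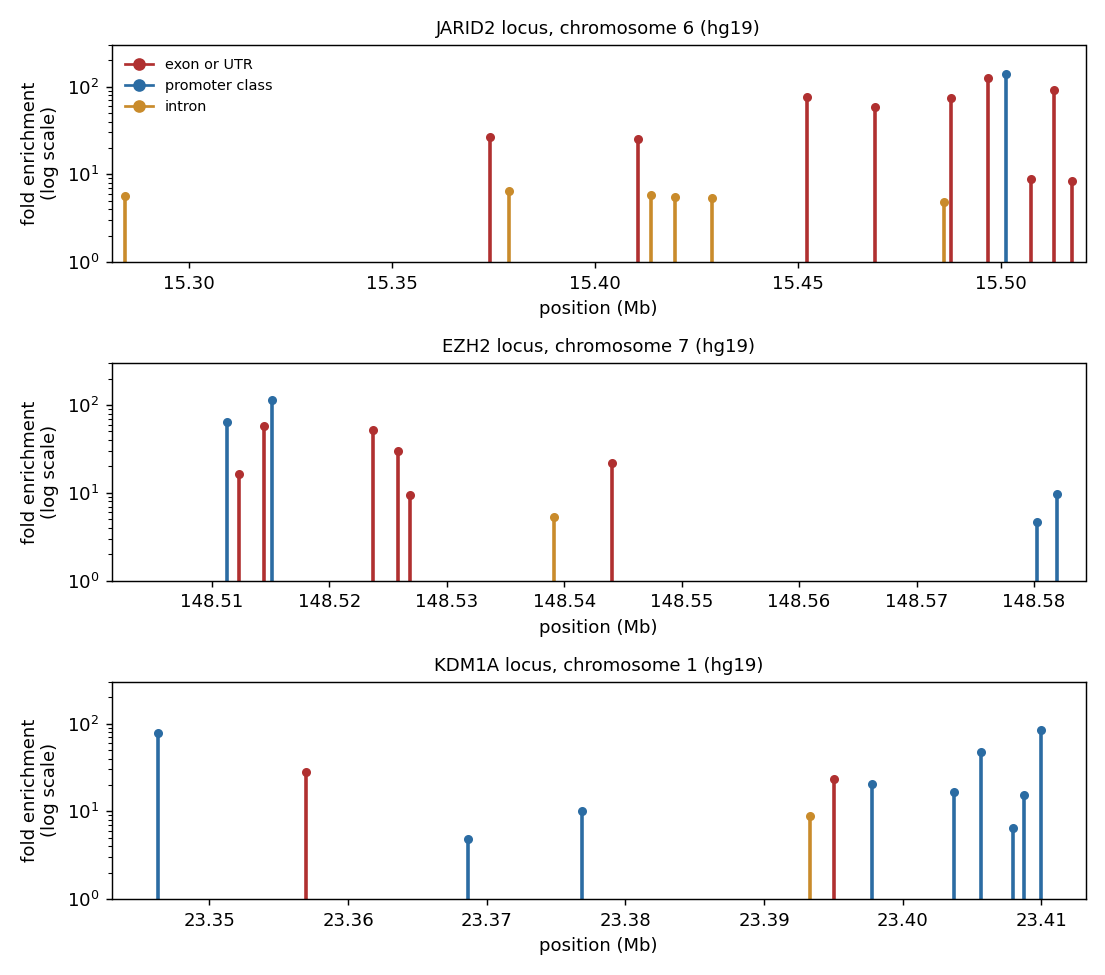
Fold enrichment (log axis) of each peak against its hg19 position in Mb for the JARID2, EZH2 and KDM1A loci, coloured by annotation class, 1 ChIP library. Exon, UTR and promoter-class peaks reach 137.44, 113.02 and 84.67 in the 3 loci, while intronic peaks stay at or below 8.83.

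Promoter peaks were found at 9 of the 14 genes of PRC2 subunits. The EZH2 peak of 64.5 lay 2 to 3 kb from an internal TSS, while the EZH2 peaks overlapping a TSS had 9.74 (FDR 16.6%) and 4.68 (33.6%). After JARID2 (137.44) and EZH2, EZH1 had 13.95 with 81 tags and an FDR of 0 on chromosome 17 (40896307 to 40897539). EPOP had 8.99 (FDR 9.70%), MTF2 7.66 (24.7%), AEBP2 6.05 (29.6%), EED 5.31 (36.3%), RBBP7 5.14 (44.2%) and PHF19 4.85 (48.2%). SUZ12 and LCOR carried only intronic peaks, RBBP4 1 intronic and 1 3′ UTR peak, the highest of these at 7.06 with an FDR of 38.3%, and no peak was given to PHF1 or EZHIP. The share of 64.3% against 33.1% of other genes gave an odds ratio of 3.64 (Fisher's exact test, two-sided, adjusted p = 0.0970), which did not pass the threshold. At an FDR of at most 5%, a limit chosen after the data were examined, JARID2, EZH2 and EZH1 remained and the adjusted p was 0.0356. Without the peaks of the JARID2, EZH2 and KDM1A loci this became 1 of 14 genes and an adjusted p of 0.784. JARID2 and EZH2 stayed in the list there as genes without a peak, so that fall was built in. A list without those genes was not tested. The closing section argues against chromatin binding as at other loci for exon and UTR peaks at JARID2 and EZH2. Their promoter-class peaks, which enter this count, were outside those tests. The call at an FDR of at most 5% therefore does not establish that JARID2 binds PRC2 genes more often.

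Olfactory receptor, keratin-associated protein and HOX genes had promoter peaks less often than other genes, and tumour suppressor genes more often. Overall 6634 of 20033 protein-coding genes (33.1%) had a promoter peak, 495 of them at an FDR of at most 5%. Of 390 olfactory receptor genes, which are silent outside sensory neurons in most tissues, 54 (13.8%) had one, an odds ratio of 0.319 (Fisher's exact test, two-sided, adjusted p = 5.93e-17) and percentile 0 among matched random lists. Keratin-associated proteins had 15 of 94 (16.0%, odds ratio 0.382, Fisher's exact adjusted p = 0.00298), but matched random lists put that share at percentile 9.77. HOX cluster genes, which set position along the body axis and are PRC2 targets in embryonic stem cells, had 4 of 39 (10.3%, odds ratio 0.230, Fisher's exact adjusted p = 0.0105, percentile 1.19). Counts of any peak, here and below, were not matched on gene length. Peaks per gene rose with transcript length (Spearman's rho 0.542 over genes with a peak), so length may enter these calls. With any peak in place of a promoter peak, HOX genes were also called as lower at 6 of 39 (odds ratio 0.141, Fisher's exact adjusted p = 1.97e-06). Keratin-associated genes were too, at 25 of 94 (odds ratio 0.280, Fisher's exact adjusted p = 8.15e-08). In the wider HOX regions 31 of 41 peaks carried symbols outside the HOX clusters, so naming by the nearest transcript may enter the HOX call. A background of genes with a peak keeps only those 6 and 25 genes, and there the odds ratios were 1.40 for HOX and 1.05 for keratin-associated genes (Fisher's exact adjusted p = 1.00 for both). In the top 25% of peaks by fold enrichment the odds ratios were 0.207 for HOX (Fisher's exact adjusted p = 0.524) and 0.734 for keratin-associated genes (Fisher's exact adjusted p = 0.916), and HOX genes had 0 of 39 at −log10 p of at least 5 (Fisher's exact adjusted p = 0.0825). Tumour suppressors had 23 of 38 (60.5%, odds ratio 3.10, Fisher's exact adjusted p = 0.00603, percentile 99.75). DLC1 (10.32, FDR 8.80%), RUNX1 (10.31, FDR 0.510%), FOXO1 (7.06, FDR 27.6%) and NF2 (7.06, FDR 8.73%) led that list. RUNX1 was its only member at an FDR of at most 5%, where the list was no longer called (odds ratio 1.07, Fisher's exact adjusted p = 0.958). That call also ended within a promoter reach of 1 kb (Fisher's exact adjusted p = 0.0703), against genes with a peak (0.399), at −log10 p of at least 5 (0.629) and in the top 25% by fold enrichment (0.916).

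**Figure D3:**
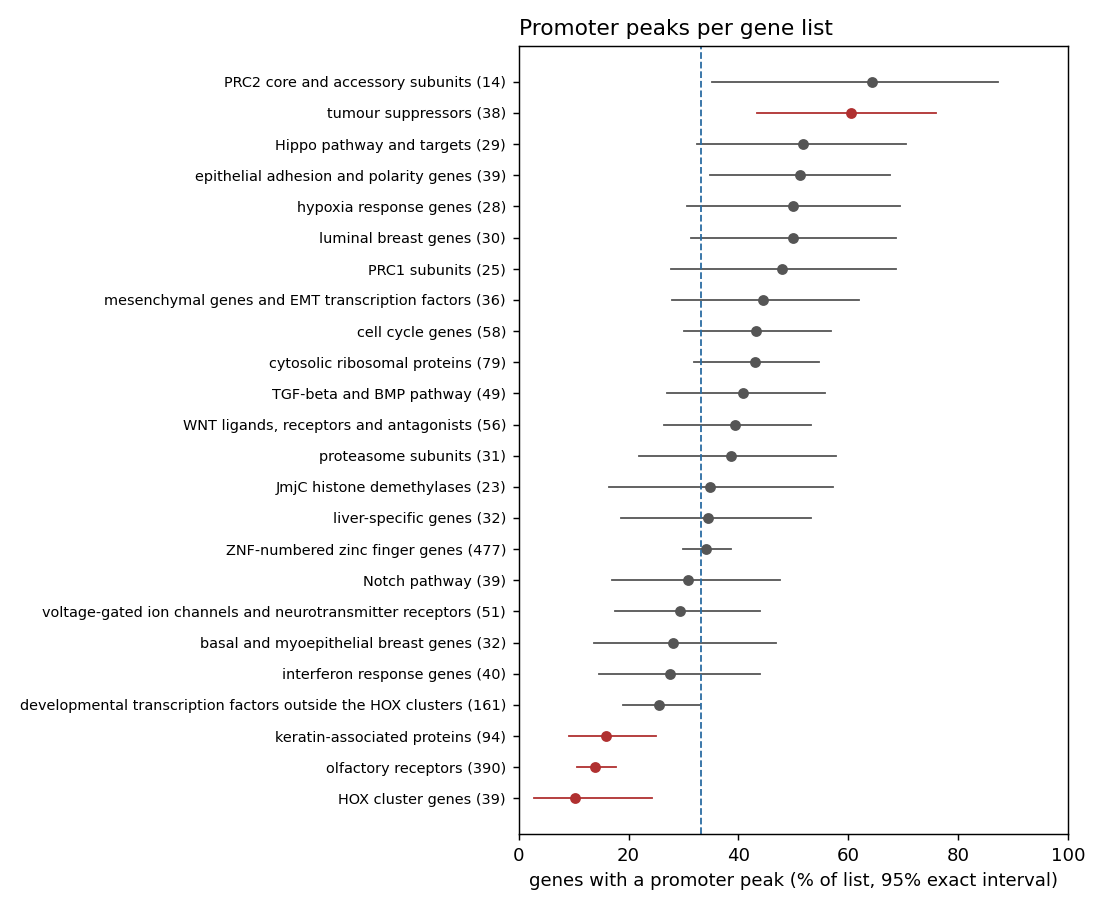
Share of genes with a promoter peak (%, points) with 95% exact binomial intervals for each of the 24 lists, the number of members in brackets, with the share of all protein-coding genes as a dashed line. The 4 lists in red passed an adjusted p of 0.05, at 10.3% (HOX), 13.8% (olfactory receptors), 16.0% (keratin-associated proteins) and 60.5% (tumour suppressors).

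The other developmental and chromatin lists did not pass the threshold. Developmental transcription factors outside the HOX clusters had promoter peaks at 41 of 161 genes (25.5%, Fisher's exact adjusted p = 0.139). Among them ZIC2 (20.35), LHX4 (14.13), SIX2 (13.08) and OSR1 (11.32) had the strongest, each with an FDR of at most 5%. PRC1 subunits had 12 of 25 (Fisher's exact adjusted p = 0.251), led by SCML2 (12.36, FDR 18.0%). JmjC demethylases had 8 of 23 (Fisher's exact adjusted p = 0.865), led by KDM3A (11.1, FDR 0) and KDM8 (7.06, FDR 13.7%). Numbered zinc finger genes had 163 of 477 (Fisher's exact adjusted p = 0.787), led by ZNF785 (30.02) and ZNF628 (13.89). At −log10 p of at least 5 the zinc finger list was called as higher (odds ratio 1.45, Fisher's exact adjusted p = 0.0334).

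No breast, epithelial or signalling list passed at the authors' threshold either. Epithelial adhesion genes had promoter peaks at 20 of 39 genes (Fisher's exact adjusted p = 0.101), with OVOL1 at 8.73, and mesenchymal genes at 16 of 36 (Fisher's exact adjusted p = 0.271), with ITGAV at 8.0 and ZEB2 at 7.95. Luminal genes had 15 of 30 (Fisher's exact adjusted p = 0.144), with the oestrogen receptor gene ESR1 at 8.83 and an FDR of 39.6%. Basal genes had 9 of 32 (Fisher's exact adjusted p = 0.808), with the laminin gene LAMA3 at 14.22 and an FDR of 0. Signalling lists gave 20 of 49 for TGF-beta and BMP (Fisher's exact adjusted p = 0.460, SMAD2 12.37 and CHRD 9.64), 22 of 56 for WNT (Fisher's exact adjusted p = 0.484, FZD5 13.25), 12 of 39 for Notch (Fisher's exact adjusted p = 0.865, DTX4 8.83) and 15 of 29 for Hippo (Fisher's exact adjusted p = 0.139, TEAD3 11.24 and STK3 9.55). The FDRs of these peaks were 27.6% for SMAD2, 7.53% for CHRD, 0.480% for FZD5, 29.7% for DTX4 and 0 for TEAD3 and STK3. Hippo genes were called at −log10 p of at least 5 (odds ratio 4.12, Fisher's exact adjusted p = 0.0113). Counting any peak, epithelial (2.59, Fisher's exact adjusted p = 0.0275), TGF-beta (2.69, 0.0111) and WNT genes (2.13, 0.0275) were called.

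Hypoxia response genes had promoter peaks more often than other genes at an FDR limit chosen after the data were examined, and more often had a peak anywhere. At the authors' threshold they had 14 of 28 (Fisher's exact adjusted p = 0.157). At an FDR of at most 5% they had 5 of 28 (17.9%) against 2.45% of other genes (odds ratio 8.66, Fisher's exact adjusted p = 0.00665). With any peak, a setting fixed beforehand, they had 23 of 28 (odds ratio 3.58, Fisher's exact adjusted p = 0.0226). Stricter limits on promoter peaks that were fixed beforehand did not give a call, with odds ratios of 3.05 at −log10 p of at least 5 (Fisher's exact adjusted p = 0.0576) and 3.17 in the top 25% by fold enrichment (Fisher's exact adjusted p = 0.0794). Nor did a reach of 1 kb (1.94, Fisher's exact adjusted p = 0.262) or a background of genes with a peak (1.09, Fisher's exact adjusted p = 1.00). The 5 genes were HIF1A (20.35), which encodes the oxygen-regulated transcription factor subunit, the glycolytic enzyme gene ALDOA (15.11), the demethylase gene KDM3A (11.1), EGLN3 (10.31), which encodes a prolyl hydroxylase, and PGK1 (10.16), the last named because of that count. The cell cycle list had 25 of 58 (Fisher's exact adjusted p = 0.247), with E2F6 at 13.99 and MCM4 at 13.82. Ribosomal protein genes had 34 of 79 (Fisher's exact adjusted p = 0.157, percentile 99.8), with RPL31 at 13.48, and were called within 1 kb of a TSS (odds ratio 2.03, Fisher's exact adjusted p = 0.0241). There were promoter peaks at 12 of 31 proteasome subunits (Fisher's exact adjusted p = 0.756), with PSMD7 at 12.36. Interferon response genes had 11 of 40 (Fisher's exact adjusted p = 0.713), with CXCL10 at 10.09 (FDR 16.9%) and CGAS at 7.88 (FDR 0). Liver genes had 11 of 32 (Fisher's exact adjusted p = 0.865) and ion channels and receptors 15 of 51 (Fisher's exact adjusted p = 0.787), their highest peaks being TAT at 7.95 (FDR 41.3%) and CACNA1A at 7.06 (FDR 43.6%). The channel list was called as lower within 1 kb (odds ratio 0.217, Fisher's exact adjusted p = 0.0241) and as higher with any peak (odds ratio 2.53, Fisher's exact adjusted p = 0.0169).

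No list differed from other genes in the height of its promoter peaks after adjustment. The median of the highest promoter fold enrichment was 7.66 for the 9 PRC2 genes, 6.77 for the 41 developmental transcription factors and 7.06 for the 20 TGF-beta and BMP genes, against 6.18 for other genes. Unadjusted permutation p-values were 0.0190, 0.0427 and 0.0394, and all 3 became 0.328 on adjustment over 23 lists. Within a promoter reach of 1 kb, PRC2 genes stood 2.86 higher than other genes (permutation test, adjusted p = 0.0252) and hypoxia genes 2.48 higher (permutation test, adjusted p = 0.0227). Without the peaks of the JARID2, EZH2 and KDM1A loci the PRC2 difference was 1.53 (permutation test, adjusted p = 0.606).

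The genes given most peaks were long genes whose peaks were about as high as those of the whole list. CNTNAP2 had 38 peaks, CTNND2 35, DLG2 34, and MGAT4C and ANKS1B 31 each. Their median fold enrichments lay between 5.60 and 6.06, against 5.95 over all peaks. CNTNAP2 had 1 peak at an FDR of at most 5%, and the other 4 genes had 0, where 1.24% of all peaks reached that limit. Over 11279 protein-coding genes with a peak, the number of peaks rose with the longest listed transcript (Spearman's rho 0.542 across genes, which are not independent replicates).

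By number, peaks were densest on chromosomes 5 and 14 and sparsest on X among the autosomes and X. Chromosomes 5 and 14 each had 28.0 peaks per Mb of the span their peaks covered, chromosome 16 had 11.6 and X had 11.4, a ratio of 2.46 between the extremes. By bases covered chromosome 20 was highest with 17.4 kb per Mb, against 16.0 for chromosome 5 and 16.2 for chromosome 14. At −log10 p of at least 5 chromosome 19 was highest with 4.95 peaks per Mb. At an FDR of at most 5% it was also the highest with 0.969 peaks per Mb and X lowest with 0.103, a ratio of 9.37. MDA-MB-231 cells are aneuploid, and these densities are not corrected for copy number.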

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

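FDR limits, and every setting without the JARID2, EZH2 and KDM1A loci, were chosen after the results were seen, and the other settings before. No paired analysis was possible because each group held 1 library. Base composition of peaks, its random-position alternative and random placement of peaks were not run, since the hg19 sequence was not used here. Of the tested main results under an alternative, 28 kept direction and side of the threshold, 10 lost their call without turning, 2 gained one and 6 turned direction. Among those that turned, HOX and keratin-associated genes against genes with a peak also lost their call. Of main counts, shares and ratios, 12 stayed close to the main value and 16 moved. For the other lists, 145 comparisons kept direction and side, 13 gained a call and 41 turned direction. Olfactory receptors kept theirs under all 7 alternatives run. Library depth is unknown. The median peak rests on 12 tags, with a counting interval of 6.20 to 20.96.

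The number of peaks fell to 8639 at −log10 p of at least 5, 665 at 10, 834 at an FDR of at most 5% and 1315 at 10%. The promoter share was 32.9% and 74.4% at the −log10 p limits, 70.7% at an FDR of at most 5%, 21.8% in the top 25% by fold, 10.7% within a reach of 1 kb and 23.04% by bases. Fewer peaks or a narrower class enter by construction. The ratio of chromosome densities was 4.76 at −log10 p of at least 5 and 9.37 at an FDR of at most 5%. Against 4 lists called in the main result (1 higher, 3 lower), 1 was called in the top 25% (lower), 2 against genes with a peak (1 higher, 1 lower), 9 with any peak (6 higher, 3 lower), 6 at −log10 p of at least 5 (3 higher, 3 lower), 5 within 1 kb (1 higher, 4 lower) and 3 at an FDR of at most 5% (2 higher, 1 lower). By fold within 1 kb, 2 lists were called against 0. Chromosome 20 was densest by bases covered and chromosome 19 at −log10 p of at least 5.

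Odds ratios of called lists lost their call as follows, and the cause was not tested. HOX genes had 0 at −log10 p of at least 5, 0.207 in the top 25% and 0 at an FDR of at most 5%, and turned to 1.40 against genes with a peak, a background that holds only 6 of them, while any peak kept the call (0.141, Fisher's exact adjusted p = 1.97e-06). Tumour suppressors had 2.27 within 1 kb, 1.38 at −log10 p of at least 5, 1.20 in the top 25%, 2.02 against genes with a peak and 1.07 at an FDR of at most 5%. Keratin-associated proteins had 0.734 in the top 25% and 0 at an FDR of at most 5%, and turned to 1.05 against genes with a peak. PRC2 subunits became called at −log10 p of at least 5 (6.86) and at an FDR of at most 5% (10.8). Without the 3 loci they were not called at those limits (3.66, adjusted p = 0.101, and 3.06, adjusted p = 0.784, Fisher's exact test) nor at the authors' threshold (2.02, uncalled with the loci too). JARID2 and EZH2 then counted as members without a peak, which lowers these odds ratios by construction. Developmental transcription factors turned to 1.08 at −log10 p of at least 5, 1.06 in the top 25%, 1.01 with any peak and 1.27 at an FDR of at most 5%, uncalled throughout.

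Other lists turned direction without being called before, and the cause was not tested. Within 1 kb, odds ratios were 0.733 for JmjC demethylases, 0.870 for luminal, 1.32 for interferon and 0.975 for liver genes. At −log10 p of at least 5 they were 0.651 for luminal, 1.30 for both basal and interferon, 0.515 for WNT, 1.04 for Notch and 0 for liver genes. In the top 25% they were 0.686 for PRC1, 0.877 for luminal, 0.744 for cell cycle, 0.767 for ribosomal, 0.544 for proteasome and 0.817 for liver genes. Against genes with a peak they were 0.622 for JmjC, 0.777 for TGF-beta, 0.810 for WNT, 1.20 for Notch and 0.856 for liver genes. With any peak they were 0.837 for ribosomal and 0.953 for zinc finger genes, and 2.53 for ion channels and receptors, called as higher (adjusted p = 0.0169, Fisher's exact test). Those channels were called as lower within 1 kb (0.217) and at −log10 p of at least 5 (0). At an FDR of at most 5% odds ratios were 0 for PRC1, mesenchymal, luminal, TGF-beta and liver genes, 0.717 for WNT, 1.27 for basal and 1.01 for interferon genes. Uncalled lists that became called in their own direction were, with any peak, epithelial (2.59), TGF-beta (2.69), WNT (2.13) and hypoxia genes (3.58). At −log10 p of at least 5 they were Hippo (4.12) and zinc finger genes (1.45), and at an FDR of at most 5% hypoxia genes (8.66). Ribosomal genes were called within 1 kb (2.03) and against genes with a peak (3.41).

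Differences in median peak height that turned, all uncalled, were 8.40 for PRC1, 1.89 for basal, 0.06 for cell cycle, 7.395 for ribosomal, 2.955 for proteasome and -1.76 for keratin-associated genes with the score in place of fold. They were 0.48 for mesenchymal genes within 1 kb, and 0.05 for mesenchymal and 0.08 for WNT genes with the mean over promoter peaks. PRC2 (2.86) and hypoxia (2.48) genes were called within 1 kb, but PRC2 genes were not without the 3 loci (1.53, permutation test, adjusted p = 0.606).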

Other observations

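The tests below were chosen after the results were seen, except the count of peaks by HOX-cluster symbols and the test of the meiosis list without the genes already seen. Several promoters with strong peaks belonged to meiosis genes, a group outside the lists fixed before the data were examined. HSF2BP had 28.77, SMC1B 27.37, ZCWPW1 25.01, CNTD1 21.22, BRME1 20.86 and SYCE2 20.37, all with an FDR of 0. A list of 72 meiosis and germ-cell genes was then written, and 7 had a promoter peak at an FDR of at most 5%. Without the 6 genes already seen, 1 of 66 did (MSH5, 5.82), an odds ratio of 0.606 (0.0151 to 3.52, Fisher's exact p = 1.00). That interval leaves open whether promoters of such genes carry strong peaks more often than others. No technical explanation was tested for this pattern.

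TOPBP1 carried 19 peaks, 7 on exons, 0 in introns and the rest in other annotation classes. Of the 19, 8 had an FDR of at most 5%, and the highest reached 49.03. A peak at the beta-globin locus named for CoTC_ribozyme (chromosome 11, 5245606 to 5247534) had 23.84 with 105 tags. These were chosen after their values were seen.

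Outside the promoter class and at an FDR of at most 5%, 38 of 244 peaks lay on exons or UTRs, and JARID2 had 7 of 7 there, RNU7-20P inside EZH2 4 of 4 and KDM1A 2 of 2. Since these genes were noticed for such peaks, a permutation test of exon labels over all 244 asked how often any gene holds as many, and gave p = 1.00e-05 for 7 and 0.0129 for 4, which argues against JARID2 on chromatin as at other loci for these peaks at JARID2 and EZH2, but 0.479 for 2 leaves it open at KDM1A. A gain in copy number of the 3 loci is argued against by exon and UTR peaks 5.01 times as high in the median as intronic ones (27.98 against 5.58, and 5.95 for all intronic peaks). Spliced cDNA of these genes in the ChIP library, for example from plasmids, may be the source but stays open, since the peak of 75.19 at the EZH2P1 pseudogene, which has EZH2 sequence without introns, was seen before that explanation was written. The highest peak of each locus (137.44, 113.02 and 84.67) is in the promoter class and outside these tests, and neither single exons nor the GH1 and beta-globin peaks were tested.

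Few promoter peaks lay at HOX genes, known PRC2 targets in other cells. Transcripts with HOX, HOTAIR, HOTTIP, MIR196 or MIR10 symbols had 10 peaks, but that count by symbol misses clone-named transcripts. The wider regions between flanking peaks of other coding genes held 41 (31 had other symbols, 7 of these in promoters). Chromosome 7 had 17 of them (26970094 to 27588872), 17 had 12 (46440488 to 46854060), 12 had 9 (54147811 to 54537634) and 2 had 3 (176996326 to 177098786). Those whole chromosomes had 26.6, 27.8, 25.6 and 21.7 peaks per Mb, and no test compared the densities. Weak peaks named for neighbours therefore stay open. An FDR of at most 5% was reached by 0 of the 41, but only by 1.24% of all peaks, so 41 are too few to show a lack. Whether strong peaks gather instead at widely expressed promoters stays open, because ribosomal protein and proteasome genes, pooled after both were seen to be raised at that limit, had 8 of 110 there (odds ratio 3.13, 1.31 to 6.45), while neither list was called alone (adjusted p = 0.184 for both, Fisher's exact test) and the pooled odds ratio in the top 25% by fold was 0.702 (0.312 to 1.39). HOX and other developmental transcription factor genes had 5 of 200 there (odds ratio 1.01, 0.324 to 2.42, Fisher's exact p = 0.821). That interval is too wide to say whether weak peaks hide an enrichment, and binding that differs in these cells remains open as an untested biological explanation.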
